A study of Mus musculus with 4 samples.

How the data were processed

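Expression was measured in 4 samples of mouse embryonic fibroblasts carrying oncogenic Ras, 1 array in each of 4 groups: p65+/+ and p65-/- cells, each before injection into immunodeficient mice and after recovery from a tumour. Per the labels, total RNA was isolated with Trizol and 6 ug were labelled with biotin by the standard Affymetrix protocol. The main values were the deposited series matrix of the authors, 1 linear signal intensity per probe set and array for 45037 probe sets. How the authors summarised the probes and normalised or scaled these signals is not given in the sources used here. The column medians were 93.4 for p65+/+ pre-injection, 92.5 for p65+/+ tumour, 87.8 for p65-/- pre-injection and 92.7 for p65-/- tumour cells, so the columns share a similar scale but not an identical distribution.

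A further table was deposited by the authors under the name of log2 ratios. Its values were checked against the series matrix and were found to hold another unit, a signed quotient of the log2 levels of 2 arrays, positive where the second-named array was higher. Between 70.3% and 89.1% of probe sets with a signal of at least 300 on both arrays matched that quotient within 0.02. Over all 45037 probe sets the share was 24.1% to 37.9%, so results from this table are less certain for weaker signals. For probe sets of this kind that differed by 2-fold or more, the sign was the same in 99.4% to 100% of cases. The table holds between 1714 and 1847 zeros per column and values up to 9463 in size, so it was used only as an alternative, through the log2 difference that each nonzero quotient implies with the lower of the 2 series matrix levels, for genes with both arrays above the floor. The third kind of data was the scanner intensity of 1004004 cells per array, not normalised per the file headers, deposited by the authors for each sample. It was used only for array-wide quality, since no map of cells to probe sets was used here. The median scanner intensity was 91.0 for p65+/+ pre-injection, 90.0 for p65+/+ tumour, 78.0 for p65-/- pre-injection and 79.0 for p65-/- tumour cells. No scan date was found in the file headers, so no batch could be assigned.

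Signals were converted to log2 after values below 1 were set to 1, with no further normalization. Probe sets were assigned to genes with the platform annotation of 2016, and gene positions and lengths came from the RefSeq gene table of the mouse assembly GRCm38. There were 34945 probe sets with 1 gene, 932 with several genes and 9160 with no gene, and the latter 2 kinds were left out of gene counts. The value of a gene was that of its single-gene probe set with the highest mean signal over the 4 arrays, and probe sets with a suffix that marks possible cross-hybridization were used only where a gene had no other. Of 18193 genes, 9010 had 2 or more probe sets. The within-gene standard deviation of the log2 differences was 0.16 for the p65+/+ tumour change, 0.35 for the p65-/- tumour change, 0.40 for the genotype difference before injection and 0.26 for that in tumour cells, from 4790, 4315, 4217 and 4624 genes with 2 or more compared probe sets.

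The floor of each array was its median signal. A gene was compared where at least 1 of the 2 arrays reached its floor, and an array under the floor was set to it, which gives an "at least" value. Genes were counted at an absolute log2 difference of 1 or more. The 4 comparisons were tumour against pre-injection cells in each genotype and p65-/- against p65+/+ cells before injection and in tumour cells. The difference of the tumour changes between genotypes and the correlations across genes were also computed. With 1 array per group there are no residual degrees of freedom within a comparison of 2 arrays, and no p-value was computed. The tumour change of p65-/- cells and the genotype difference before injection share the p65-/- pre-injection array. Likewise, the tumour change of p65+/+ cells and the genotype difference in tumour cells share the p65+/+ tumour array.

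There were 28 gene lists with 622 entries, of which 575 had a probe set of their own. They covered NF-kB subunits and regulators, NF-kB target genes, chemokines and cytokines, interferon-stimulated genes, MHC class I and antigen processing, immune surveillance ligands, Ras-MAPK output, cell cycle, p53 targets and CDK inhibitors, apoptosis, collagens and matrix, matrix proteases, contractile and SRF genes, mesenchymal regulators, growth factors, hypoxia and glycolysis, ER stress and ATF4 targets, NRF2 and antioxidant genes, cholesterol synthesis, Hox genes, immediate early and heat shock genes, sex-linked genes, and markers of macrophages, endothelium, lymphocytes and granulocytes, epithelium, muscle and fat cells. Some genes stand in more than 1 list. The median log2 difference of a list was set against 10000 random lists of the same size, drawn within 20 bins of mean signal, and a list was said to stand apart at or below percentile 2.5 or at or above percentile 97.5. Lists with fewer than 5 compared members were given no percentile. The percentile describes these arrays and is not a test of genotype or tumour growth.

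Named genes were, for each comparison, the 8 highest and 8 lowest with both arrays above the floor, the 4 largest "at least" values in each direction, all NF-kB subunits and regulators at 2-fold or more, and up to 4 members of each other list. For the difference of the tumour changes they were the 5 highest and the 5 lowest with all 4 arrays above the floor, and predicted genes were passed over. Members named to spell out a short count, or because they recur between comparisons, were chosen after their values were seen. The samples, comparisons, floor, threshold, lists, rule for named genes and first set of alternatives were fixed before the data were examined.

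The first set of alternatives was centring each array on its median, quantile normalization, the authors' deposited table of quotients, a floor at the 25th or 70th percentile or none, the mean of all probe sets of a gene, and a threshold of 4-fold. Scaling to the 75th percentile, cyclic loess and the p65-/- tumour array in place of the p65-/- pre-injection array were added after the data were seen. Median centring and scaling to the 75th percentile add 1 constant to all genes of a comparison. They cannot change the percentile of a list except through the draw of random lists, and they are not counted where a number of alternatives is given for a list. Fewer random lists were drawn for the alternatives than for the deposited values, except for the percentiles printed for the substituted array. A percentile can thus differ slightly between settings by the draw alone, which matters for a list near a limit. The counting and list procedures were tested on simulated data with noise of standard deviation 0.25 on the log2 scale. They found 11.9% of 67 genes shifted by 0.5, 91.0% of 67 shifted by 1.5 and 100% of 66 shifted by 3 on the log2 scale, and counted 0.358% of 11729 unshifted genes. Of 200 random lists without a shift 5% stood apart, as did 88% of 200 lists shifted by 0.3. The single genes that were shifted all had signals far above the floor. The noise was independent between probe sets and arrays, with no array-wide shift and no genes that vary together. These rates therefore do not carry over to genes near the floor, to lists of genes that vary together or to an array with generally lower signal. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for quantile and cyclic loess normalization.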

Results

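Gene expression was measured in mouse embryonic fibroblasts on 4 Affymetrix arrays, 1 per group. The cells were wild type for Rela, the gene of the p65 subunit of the transcription factor NF-kB (p65+/+), or lacked it (p65-/-), and all carried an oncogenic form of Ras brought in by a retrovirus. For each genotype, RNA came from the cultured cells before injection into immunodeficient mice (pre-injection cells) and from cells taken out of a tumour, returned to culture and selected with hygromycin for 2 weeks (tumour cells). The number of mice and tumours behind each array is not given in the sources used here. Each array gave a signal for 45037 probe sets, which covered 18193 genes with at least 1 probe set of their own. The number of arrays limits the precision: with 1 array per group there was no replicate check and no test, and "higher" and "lower" describe the ratio of 2 arrays. Genotype and line of cells cannot be told apart in this layout. A gene was counted as higher or lower at a difference of 2-fold or more. Where 1 of the 2 arrays lay under its floor, which was the median signal of that array, the floor took its place and the fold is given as "at least". Each gene list was set against 10000 random lists of genes with similar signal, and its median log2 difference is given with its percentile among them.

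Rela itself was measured first, as a check of the genotype labels. Its signal was 1479 in p65+/+ pre-injection cells and 1457 in p65+/+ tumour cells, and 214 and 209 in p65-/- pre-injection and tumour cells. The p65-/- level was thus 14.5% of the p65+/+ level before injection and 14.4% in tumour cells, or 6.91-fold and 6.96-fold lower. Both p65-/- values lay above the floors of their arrays, 87.8 and 92.7. Rela had 1 probe set, and where that probe set lies relative to the deleted part of the gene is not known here.

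The p65-/- pre-injection array differed from the other 3 arrays in its deposited signal. It had 11153 probe sets with a signal of at least 200, compared with 13419 on the p65+/+ pre-injection array, 13333 on the p65+/+ tumour array and 13015 on the p65-/- tumour array. The median scanner intensity was 78 and 79 on the p65-/- pre-injection and tumour arrays and 91 and 90 on the p65+/+ pre-injection and tumour arrays, and the 75th percentile was 158 and 169, and 210 and 193. Across 10082 genes, the log2 signals of the p65+/+ arrays had a correlation of 0.976 with each other. The p65-/- tumour array had a correlation of 0.947 with the p65+/+ pre-injection array and 0.867 with the p65-/- pre-injection array. Genes are not independent replicates, and these coefficients describe the arrays only. For p65-/- against p65+/+ pre-injection cells, the counts were therefore also taken with the p65-/- tumour array in its place, a substitution chosen after the data were seen. It sets p65-/- tumour cells against p65+/+ pre-injection cells. Genotype and tumour state are thus mixed, and p65-/- pre-injection cells are not measured by it. Quantile normalization and scaling to the 75th percentile moved the median log2 difference of all genes compared before injection from -0.02 to 0.24 and 0.35, and that of the p65-/- tumour change from 0.03 to -0.18 and -0.25. The sign of a list median can turn with such a shift, so its percentile among random lists is given beside it.

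The first comparison asked how p65-/- and p65+/+ cells differed before injection. Among genes with both arrays above the floor, the largest decreases in p65-/- cells included Ereg, a ligand of the epidermal growth factor receptor, at 21.4-fold lower, Prxl2a at 21.2-fold, Slpi, a secreted protease inhibitor, at 15.0-fold and Rictor, a subunit of an mTOR complex, at 14.9-fold lower. The monocyte chemokine Ccl2 was 13.5-fold lower, with a signal of 2671 in p65+/+ and 198 in p65-/- cells. The acute-phase protein gene Saa3 was 14.4-fold lower, the prostaglandin E synthase gene Ptges 13.5-fold, the fibroblast growth factor gene Fgf7 13.1-fold and the cytokine gene Il33 13.0-fold lower. Signals that dropped under the floor in p65-/- cells included the matrix proteoglycan gene Dcn, at least 76.0-fold lower, the retinoic acid binding protein gene Crabp1, at least 38.4-fold, the ceruloplasmin gene Cp, at least 36.0-fold, and Tmem176b, at least 30.0-fold lower. Higher genes included Igfbp6 and Igfbp4, which encode binding proteins of insulin-like growth factors, at 16.7-fold and 11.5-fold, the epoxide hydrolase gene Ephx1 at 13.3-fold, Dynap at 7.54-fold and the enolase gene Eno3 at 6.62-fold. Ifitm1, an interferon-induced gene, was at least 29.0-fold higher, the water channel gene Aqp1 at least 10.9-fold, Psrc1 at least 8.79-fold and the homeobox gene Hoxa11 at least 8.65-fold higher. Dcn passed 2-fold in 1 of its 2 compared probe sets.

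NF-kB target genes were lower in p65-/- pre-injection cells. Of 28 compared, 16 were lower and 1 was higher, the median was -1.48 and it lay at percentile 0 of random lists. Cxcl5, a neutrophil chemokine, was at least 25.9-fold lower, Ptx3, a secreted pattern recognition protein, at least 11.4-fold, the metalloproteinase gene Mmp3 10.7-fold and Ptgs2, a prostaglandin synthase, 9.67-fold lower. The member that was higher was the chemokine gene Ccl5, at 2.85-fold. NF-kB subunits and regulators had 7 of 15 lower and 0 higher (median -0.85, percentile 0.72). Besides Rela they included the regulator genes Nfkbia at 3.15-fold, Nfkbiz at 4.64-fold, Nfkbie at least 2.73-fold and Bcl3 at 2.30-fold lower. The deubiquitinase gene Cyld was 3.18-fold and the kinase subunit gene Ikbkg 2.79-fold lower, Ikbkg in 1 of its 6 compared probe sets. That list no longer stood apart with the floor at the 70th percentile or with the mean of all probe sets of a gene. Chemokines and cytokines had 9 of 28 lower and 1 higher (median -0.16, percentile 2.63, and 0.22 at percentile 3.10 after scaling to the 75th percentile). The list stood apart below random lists under 6 of 8 alternatives that can change its place. Among them Lif was 7.21-fold and Kitl 4.25-fold lower.

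Other lists showed genes lower in p65-/- pre-injection cells without standing apart from random lists. Mesenchymal regulators had 8 of 17 lower and 0 higher (median -0.82, percentile 3.84, standing apart under 2 of 8 alternatives), with the surface marker Thy1 12.7-fold lower, the transcription factor genes Snai2 4.29-fold and Prrx1 3.36-fold, and the receptor gene Pdgfra 3.42-fold lower. Growth factors and receptors had 9 of 29 lower and 3 higher (median -0.23, percentile 19.7, with 0.24 at percentile 54.1 after quantile normalization and 0.14 at percentile 19.8 after scaling to the 75th percentile). Wnt5a was at least 10.2-fold lower and the vascular growth factor gene Vegfa 3.86-fold lower. Collagens and matrix genes had 8 of 32 lower and 3 higher (median -0.22, percentile 37.1, with 0.04 at percentile 32.7 and 0.15 at percentile 36.5 under those 2 settings), with Col12a1 11.3-fold and the proteoglycan gene Vcan 7.21-fold lower. Cholesterol synthesis genes had 6 of 14 lower, such as Idi1 at 5.13-fold, and 0 higher (median -0.59, percentile 15.5). Matrix proteases and inhibitors had 4 of 19 lower and 0 higher (percentile 5.58), and apoptosis regulators 5 of 20 lower, such as the caspase inhibitor Xiap at 9.14-fold, and 0 higher (percentile 17.1).

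A few lists lay high among random lists in that comparison. Hypoxia and glycolysis genes had 2 of 21 higher, the oxygen sensor gene Egln3 at 2.76-fold and the phosphofructokinase gene Pfkl at 2.41-fold, and Vegfa lower (median 0.20, percentile 99.6, lost after quantile normalization). ER stress and ATF4 targets had 2 of 20 higher, such as the transcription factor gene Atf5 at 2.97-fold, and 1 lower, the chaperone gene Hsp90b1 at 3.75-fold (median 0.19, percentile 98.6). Cell cycle genes had 8 of 31 lower and 0 higher, with the kinase gene Bub1 8.32-fold, the proliferation marker Mki67 7.25-fold and the motor gene Kif11 4.86-fold lower. Their median, 0.08, was above that of random lists, -0.27 (percentile 98.8), while their mean was -0.36. The p53 targets and CDK inhibitors went both ways, with 4 of 15 higher and 5 lower (median 0.13, mean -0.13, percentile 95.5, standing apart under 2 of 8 alternatives). The inhibitor gene Cdkn1a was 4.09-fold and Phlda3 4.62-fold higher, while Cdkn2b was at least 13.6-fold and Cdkn2a at least 3.17-fold lower.

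In total 2245 of 12584 compared genes were lower and 259 higher in p65-/- pre-injection cells, so 89.7% of the 2-fold differences were decreases. That share was 63.2% after quantile normalization, with 886 higher, and 64.99% after scaling to the 75th percentile, with 795 higher, but 83.2% with cyclic loess and 86.45% with each array centred on its median. With the p65-/- tumour array in place of the pre-injection array, 450 genes were lower and 219 higher. NF-kB target genes then had 16 of 27 lower and 1 higher (median -1.18, percentile 0), mesenchymal regulators 2 of 17 lower and 0 higher, and cholesterol synthesis genes 0 lower and 0 higher. The place of 7 lists changed with that substitution, which mixes genotype with tumour state. Chemokines and cytokines (median -0.19, percentile 0.56), Ras-MAPK output genes (-0.31, 0.35), NRF2 and antioxidant genes (-0.25, 0.69) and immediate early and heat shock genes (-0.59, 0.01) then stood apart below random lists. The p53 targets and CDK inhibitors (0.59, 100), collagens and matrix genes (0.16, 99.93) and Hox genes (0.17, 99.5) stood apart above them.

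The same genotype comparison was made in tumour cells. Among the largest decreases in p65-/- tumour cells, the activin-binding protein gene Fst was 27.0-fold lower, with a signal of 5908 in p65+/+ and 218 in p65-/- tumour cells, Il33 23.7-fold, Cp 21.5-fold, Slpi 15.1-fold and Ereg 14.6-fold lower. The methylthioadenosine phosphorylase gene Mtap was 17.3-fold lower, Emb 16.7-fold and the phosphodiesterase gene Pde3b 13.1-fold lower. Dcn was at least 65.4-fold lower, Prxl2a at least 37.6-fold, the thrombomodulin gene Thbd at least 35.1-fold and the proteoglycan gene Lum at least 23.2-fold lower. Higher genes included Tmem45a at 15.7-fold, the chemokine gene Cxcl12 at 10.98-fold, Ephx1 at 9.90-fold, the ezrin gene Ezr at 8.65-fold, Aqp1 at 6.88-fold and the matrix gene Fbln2 at 6.50-fold. At least 37.0-fold higher was the centriole gene Cep128, at least 28.7-fold the imprinted adaptor gene Grb10, at least 23.7-fold the keratin gene Krt19 and at least 22.4-fold the receptor gene Npy5r. Mospd1 was 13.2-fold higher, and the log2 difference implied for it by the authors' deposited table was -0.31. Dcn, Cep128 and Ezr each passed 2-fold in 1 of 2 compared probe sets.

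NF-kB target genes had 17 of 27 lower and 1 higher in p65-/- tumour cells (median -1.31, percentile 0). Mmp3 was at least 18.7-fold lower, the iron-binding protein gene Lcn2 at least 16.1-fold, the cytokine gene Il6 at least 12.1-fold and Ccl2 6.60-fold lower. The exception was the neutrophil chemokine gene Cxcl1, at least 17.7-fold higher. In the list, 14 genes were lower in p65-/- cells in both states and 0 were higher in both, and the 14 were Nfkbia, Nfkbie, Birc3, Ccl2, Ccl7, Cxcl5, Il6, Lif, Mmp3, Ptgs2, Saa3, Lcn2, Sod2 and Ptx3. NF-kB subunits and regulators had 4 of 14 lower and 0 higher (median -0.33, percentile 1.69), namely Rela, Relb at least 2.55-fold, Nfkbia 2.47-fold and Nfkbie at least 2.42-fold lower, a list that lost its place under 4 of 7 alternatives, which were quantile normalization, the authors' deposited table, the floor at the 70th percentile and the mean of all probe sets. Chemokines and cytokines had 8 of 24 lower and 3 higher (median -0.23, percentile 0.22), the higher ones being Cxcl1, Cxcl12 and Cx3cl1, the last at 4.31-fold.

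**Figure D1:**
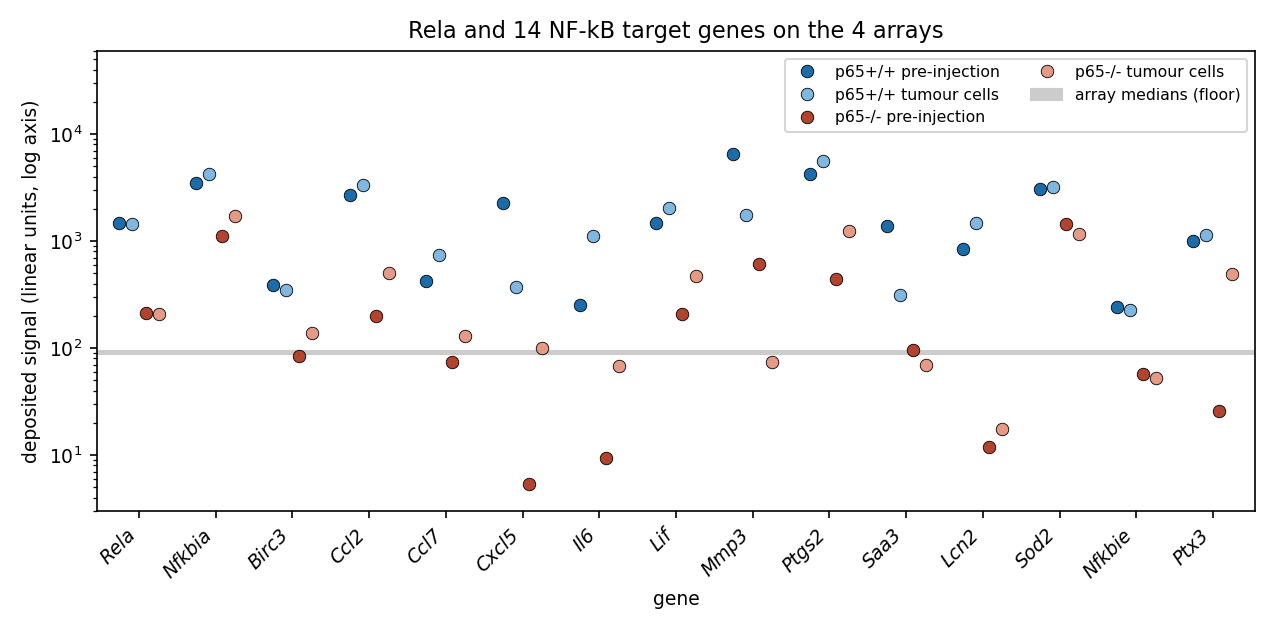
Signal on each of the 4 arrays, on a log axis, for Rela and the 14 NF-kB target genes that were at least 2-fold lower in p65-/- than in p65+/+ cells both before injection and in tumour cells. Each point is 1 array, the grey band spans the array medians from 87.77 to 93.36 used as floors, and the Rela points lie at 1479 and 1457 for p65+/+ and at 214 and 209 for p65-/- cells.

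Ras-MAPK output genes lay low among random lists in p65-/- against p65+/+ tumour cells, with 7 of 23 lower and 0 higher (median -0.73, percentile 0). Besides Ereg they included the feedback inhibitor Spry4, at least 8.94-fold lower, the ERK phosphatase gene Dusp6 at 4.001-fold, Dusp5 at 3.41-fold and the transcription factor gene Egr1 at 3.11-fold. Before injection the list had 3 of 23 lower and 2 higher (median -0.04, percentile 86.3). With the p65-/- tumour array in place of the p65-/- pre-injection array 6 of 23 were lower and 0 higher (median -0.31, percentile 0.35). That comparison uses the same p65-/- tumour array and mixes genotype with tumour state, so it is no measure of pre-injection cells. The list entry Hras1 had no probe set of its own, and the level of the introduced Ras on each array was not checked. NRF2 and antioxidant genes had 4 of 19 lower and 1 higher (median -0.38, percentile 0.24), with the superoxide dismutase gene Sod3 at least 16.1-fold, the metallothionein gene Mt2 5.99-fold, Nqo1 5.07-fold and Sod2 2.70-fold lower. Before injection 4 of 20 were lower and 2 higher (median -0.28, percentile 23.5, with 0.09 at percentile 23.1 after scaling to the 75th percentile), and with the substituted array 4 of 20 were lower and 1 higher (median -0.25, percentile 0.69). ER stress and ATF4 targets had 3 of 20 lower and 0 higher (median -0.30, percentile 0.57), the cystine transporter gene Slc7a11 at least 3.17-fold, Chac1 2.34-fold and Atf5 2.04-fold. This list lay high before injection (median 0.19, percentile 98.6). With the substituted array it also lay high, with 0 of 20 lower and 0 higher (median 0.15, percentile 99.15). The p65+/+ tumour array, shared with the p65+/+ tumour change, had the list higher than before injection (median 0.43, percentile 100). Immediate early and heat shock genes had 2 of 11 lower and 0 higher (median -0.49, percentile 0.54), Egr1 and Hspb1, the latter at 3.08-fold, but did not stand apart with the floor at the 70th percentile or in the authors' deposited table. Mesenchymal regulators had 4 of 17 lower, such as Pdgfra at 4.01-fold and Twist2 at 3.87-fold, and 1 higher, the cadherin gene Cdh11 at least 8.77-fold (median -0.37, percentile 0.79, lost in the authors' deposited table). Cholesterol synthesis genes had 0 of 14 lower and 0 higher, with a median of -0.36 at percentile 1.54 that did not stand apart with the floor at the 70th percentile or with the mean of all probe sets.

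The p53 targets and CDK inhibitors again went both ways in tumour cells, with 6 of 17 higher and 3 lower (median 0.37, percentile 99.98). The cyclin gene Ccng1 was 6.13-fold, Phlda3 4.197-fold and Cdkn1a 3.24-fold higher, and Cdkn2b at least 9.89-fold, Cdkn2a at least 4.01-fold and Cdkn2c 2.49-fold lower. The genes Cdkn2a, Cdkn2b and Cdkn2c were lower, and Cdkn1a, Phlda3 and Zmat3 higher, in p65-/- cells in both states. Collagens and matrix genes had 8 of 31 higher and 7 lower, with a median of 0.41 at percentile 100 and a mean of -0.09. Higher members included Fbln2, Col1a1 at 2.91-fold and the fibronectin gene Fn1 at 2.37-fold, and lower ones Dcn, Lum and the tenascin gene Tnc at 5.08-fold. Hox genes had 5 of 23 higher and 3 lower (median 0.19, percentile 99.5, lost in the authors' deposited table and with the floor at the 25th percentile), with Hoxa11 at least 9.99-fold and Hoxd13 at least 5.22-fold higher and Hoxb6 at least 3.47-fold lower. Before injection the Hox list had 3 of 21 higher and 2 lower (percentile 91.0, standing apart under 4 of 8 alternatives). Cell cycle genes had 1 of 31 lower, the cyclin gene Ccne2 at 4.88-fold, and 0 higher (median 0.21, percentile 99.95). Growth factors and receptors had 7 of 30 lower, such as Wnt5a at 7.55-fold and the bone morphogenetic protein gene Bmp4 at 4.08-fold, and 2 higher (median -0.10, percentile 11.6, standing apart under 1 of 7 alternatives). Matrix proteases and inhibitors had 5 of 19 lower and 2 higher (percentile 30.9), contractile and SRF genes 2 of 18 lower and 2 higher (percentile 91.3, standing apart under 3 of 7), apoptosis regulators 2 of 20 lower and 1 higher (percentile 60.2), and hypoxia and glycolysis genes 0 of 21 lower and 1 higher (percentile 94.5, standing apart under 2 of 7).

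In tumour cells 655 of 11977 compared genes were lower and 317 higher in p65-/- cells. Of the genes compared in both states, 394 were lower in p65-/- cells in both, compared with 123 if the states were independent, and 71 were higher in both, compared with 6.22. The 394 genes made up 17.6% of those lower before injection and 61.0% of those lower in tumour cells. Across 10082 genes the log2 genotype differences of the 2 states, which share no array, had a Pearson correlation of 0.436 and a Spearman correlation of 0.442, and in the authors' deposited table, where a few very large values occur, the coefficients were -0.0027 and 0.320.

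In p65+/+ cells, tumour cells were compared with pre-injection cells. The labels give hygromycin selection for the tumour cells only. Growth in the animal, return to culture and selection therefore cannot be told apart, here or in the tumour change of p65-/- cells. The matrix proteoglycan gene Lum was 12.7-fold higher in tumour cells, with a signal of 169 before and 2151 after, the steroid dehydrogenase gene Akr1c18 9.46-fold, Fst 7.95-fold, Dynap 6.36-fold and the urea transporter gene Slc14a1 6.00-fold higher. Igfbp4 was 5.90-fold higher, the secreted chaperone gene Clu 5.74-fold and Mid1ip1 4.83-fold higher. Kctd4 was at least 4.97-fold, the vesicle transport gene Sar1b at least 4.44-fold, Pcdh17 at least 4.03-fold and the alcohol dehydrogenase gene Adh7 at least 3.92-fold higher. Lower genes included Tmem45a at 9.35-fold, Cxcl5 at 6.18-fold, Tpd52l1 at 5.06-fold, the metalloproteinase gene Mmp10 at 5.04-fold, Cxcl12 at 4.78-fold, Kctd15 at 4.51-fold, and Saa3 and Nsg1 at 4.41-fold each. The neurofilament gene Nefl was at least 9.66-fold, the imprinted gene Ndn at least 7.14-fold, Bhlhb9 at least 7.12-fold and the bone morphogenetic protein gene Bmp2 at least 6.57-fold lower. Kctd4 passed 2-fold in 1 of its 2 compared probe sets.

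ER stress and ATF4 targets lay highest among the lists in p65+/+ tumour cells, with 3 of 20 higher and 0 lower (median 0.43, percentile 100). They were Chac1, a glutathione-degrading enzyme, at 3.84-fold, Atf5 at 3.20-fold and Slc7a11 at 2.65-fold. NRF2 and antioxidant genes had 2 of 20 higher and 0 lower (median 0.14, percentile 98.7), the transferase gene Gstm2 at 2.42-fold and the quinone reductase gene Nqo1 at 2.12-fold. Ras-MAPK output genes had 2 of 22 higher and 0 lower (median 0.21, percentile 99.8), the receptor gene Epha2 at 2.09-fold and Spry4 at 2.05-fold, the latter in 1 of 4 compared probe sets. NF-kB target genes went both ways, with 2 of 26 higher, Il6 at 4.43-fold and Ccl5 at 2.54-fold, and 3 lower, Cxcl5, Saa3 and Mmp3, the last at 3.75-fold (median 0.19, percentile 99.97). NF-kB subunits and regulators had 0 of 14 higher and 0 lower (median -0.09, percentile 14.2). Chemokines and cytokines had 3 of 25 higher and 3 lower, among them Cx3cl1 at 3.32-fold lower (median 0.08, mean -0.01, percentile 97.6), and interferon-stimulated genes 1 of 17 higher, Ifit2 at 2.15-fold, and 0 lower (median 0.13, percentile 99.4). Mesenchymal regulators had 1 of 17 higher, Twist2 at 2.5-fold, and 1 lower, Cdh11 at least 6.33-fold (median 0.18, percentile 98.9), and p53 targets and CDK inhibitors 0 of 15 higher and 0 lower (median 0.14, percentile 98.0). The last 4 lists lost their place outside the random range under 1 or more of the alternatives.

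Cell cycle genes lay low in p65+/+ tumour cells, with 0 of 31 higher and 0 lower at 2-fold (median -0.20, percentile 0.01). Collagens and matrix genes also lay low (median -0.20, percentile 0.01), with 1 of 32 lower, Col6a3 at 2.58-fold, and 3 higher, Lum, the thrombospondin gene Thbs1 at 4.61-fold and Tnc at 3.40-fold. Matrix proteases and inhibitors had 3 of 20 lower, Mmp10, Mmp3 and Mmp13, the last at least 5.52-fold, and 1 higher, Adamts1 at 2.33-fold (median 0.09, mean -0.21, percentile 94.4, standing apart under 2 of 7 alternatives). Contractile and SRF genes had 2 of 18 higher, the matricellular genes Ccn2 at 3.67-fold and Ccn1 at 2.52-fold, and 1 lower, Tagln at 2.07-fold (percentile 48.4). Growth factors and receptors had 2 of 27 higher and 1 lower (percentile 69.6), apoptosis regulators 0 of 21 higher and 2 lower, such as Bcl2 at 2.497-fold in 1 of 3 compared probe sets (percentile 6.99), and hypoxia and glycolysis genes 1 of 21 higher and 0 lower (percentile 92.0). Cholesterol synthesis genes (0 higher and 0 lower of 14, percentile 53.5), Hox genes (0 and 0 of 15, percentile 77.6, standing apart under 1 of 7 alternatives) and immediate early and heat shock genes (0 and 0 of 11, percentile 11.1) had no member at 2-fold. In total 112 of 11695 compared genes were higher and 89 lower, 1.72% of those compared, and 19 of the higher and 33 of the lower ones were "at least" values. In the authors' deposited table the counts were 605 and 616.

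In p65-/- cells, many more genes differed between tumour and pre-injection cells, and most were higher. The largest increases with both arrays above the floor were in the imprinted adaptor gene Grb10 at 28.5-fold, the heparan sulphate sulphotransferase gene Hs6st2 at 17.7-fold, Cxcl1 at 16.4-fold, Fbln2 at 14.5-fold, the surface protein gene Cd24a at 14.01-fold, the semaphorin gene Sema3c at 13.6-fold and the signal peptidase gene Spcs3 at 10.5-fold. Cep128 was at least 39.0-fold, Mospd1 at least 34.3-fold, Npy5r at least 23.6-fold and Gulp1 at least 10.3-fold higher. Lower genes included the neurotrophin receptor gene Ntrk3 at 6.91-fold, the malonyl-CoA decarboxylase gene Mlycd at 6.55-fold, Shisa7 at 6.35-fold, the phosphate transport gene Ank at 6.24-fold, Glipr1 at 6.07-fold, the potassium channel gene Kcnn4 at 6.03-fold, Cd34 at 5.97-fold and Upp1, a uridine phosphorylase, at 5.23-fold. Nefl was at least 45.1-fold, Igfbp6 at least 32.8-fold, Ifitm1 at least 29.2-fold and Dynap at least 9.10-fold lower. Ntrk3 passed 2-fold in 1 of its 3 compared probe sets and Cep128 in 1 of 2. The Rela signal was 214 before injection and 209 in tumour cells.

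Ras-MAPK output genes lay low among random lists in p65-/- tumour against pre-injection cells, with 6 of 23 lower and 2 higher, while random lists had a median of 0.19 (median -0.25, percentile 0.03). Spry4 was at least 4.14-fold, the ERK phosphatase genes Dusp4 3.51-fold and Dusp6 2.98-fold and the transcription factor gene Fosl1 2.49-fold lower. NF-kB target genes had 8 of 24 higher and 3 lower (median 0.45, percentile 97.7, lost with the mean of all probe sets and with cyclic loess). Besides Cxcl1 the higher ones included Ptx3, at least 5.65-fold, and Ptgs2 at 2.85-fold, and the lower ones Mmp3, at least 6.60-fold, and Ccl5 at 2.71-fold. NF-kB subunits and regulators had 4 of 14 higher and 0 lower, Cyld at 3.25-fold, Nfkbiz at 2.57-fold, Tnfaip3 at 2.43-fold and Ikbkg at 2.38-fold (median 0.65, percentile 98.9), p53 targets and CDK inhibitors 7 of 14 higher, such as Ccng1 at 4.18-fold, and 0 lower (median 0.58, percentile 97.8), and Hox genes 3 of 20 higher and 0 lower (median 0.17, percentile 98.9). The subunit, p53 and Hox lists stood apart with the deposited values but not under most of the alternatives, and the Hox median was -0.14 at percentile 63.3 after quantile normalization and -0.12 at percentile 98.8 after scaling to the 75th percentile, which shifts all genes alike.

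Several lists had many higher members in p65-/- tumour cells and lay within the random range with the deposited values. Collagens and matrix genes had 10 of 29 higher and 2 lower (median 0.39, percentile 91.2, and 98.9 after quantile normalization, standing apart under 2 of 7 alternatives), with the cross-linking enzyme gene Lox at 6.91-fold and Col12a1 at 4.17-fold higher and Thbs2 4.02-fold lower. Mesenchymal regulators had 6 of 17 higher and 0 lower (median 0.58, percentile 93.2), such as Cdh11 at least 9.25-fold, Thy1 at 4.61-fold and Snai2 at 3.85-fold. Cell cycle genes had 6 of 31 higher and 0 lower, such as Bub1 at 4.93-fold, Kif11 at 4.70-fold and Mki67 at 4.18-fold. Their median of 0.21 lay at percentile 50.6, beside 0.20 for random lists, and was -0.10 at percentile 43.5 after quantile normalization and -0.08 at percentile 49.2 after scaling to the 75th percentile. Chemokines and cytokines had 4 of 22 higher, with Cxcl12 at 7.92-fold, and 1 lower (median -0.03, mean 0.38, percentile 34.1). Contractile and SRF genes had 4 of 18 higher, with Tagln at 5.97-fold, and 0 lower (percentile 77.8), cholesterol synthesis genes 4 of 14 higher and 0 lower (percentile 69.9), and growth factors and receptors 3 of 31 higher and 3 lower (percentile 54.4). Apoptosis regulators had 2 of 18 higher and 0 lower (percentile 69.6, standing apart under 1 of 7), matrix proteases and inhibitors 3 of 19 and 2 (percentile 38.5), hypoxia and glycolysis genes 1 of 21 and 1 (percentile 4.01, standing apart under 3 of 7 alternatives), ER stress and ATF4 targets 2 of 19 and 0 (percentile 32.8), NRF2 and antioxidant genes 1 of 17 and 0 (percentile 27.9), and immediate early and heat shock genes 1 of 11 and 1 (percentile 6.56).

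In total 1705 of 12443 compared genes were higher and 184 lower in p65-/- tumour cells. On the p65-/- tumour array, 1522 of the 1705 genes, or 89.3%, lay within 2-fold of the p65+/+ pre-injection array, 101 lay above it and 82 below it, and 1464 of the 1705 were lower in p65-/- than in p65+/+ pre-injection cells, a comparison that uses the same p65-/- array. The lower genes numbered 428 after quantile normalization and 357 after scaling to the 75th percentile, where the higher ones numbered 1088. No other p65-/- array could take the place of the pre-injection array in this comparison.

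The tumour changes of the 2 genotypes, which share no array, were then set against each other. Across 10082 genes their Pearson correlation was -0.018 and their Spearman correlation -0.007. Of 11328 genes compared in both, 19 were higher in tumour cells of both genotypes, compared with 14.8 if the genotypes were independent, and 9 were lower in both, compared with 1.17. A further 20 genes were higher in p65+/+ and lower in p65-/- tumour cells, compared with 1.42, and 25 were lower in p65+/+ and higher in p65-/- tumour cells, compared with 12.1. Genes of the first kind included Igfbp6, Dynap, Clu, Akr1c18 and Spry4, and genes of the second kind Ndn, Cdh11, Cyp1b1, Abcg2 and Tagln. Cxcl12 was 4.78-fold lower in p65+/+ and 7.92-fold higher in p65-/- tumour cells, which gave a difference between the changes of 5.24 on the log2 scale. The difference was at least 1 on the log2 scale in favour of p65-/- cells for 1794 genes and in favour of p65+/+ cells for 298 genes. It was not tested, and it contains the p65-/- pre-injection array.

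**Figure D2:**
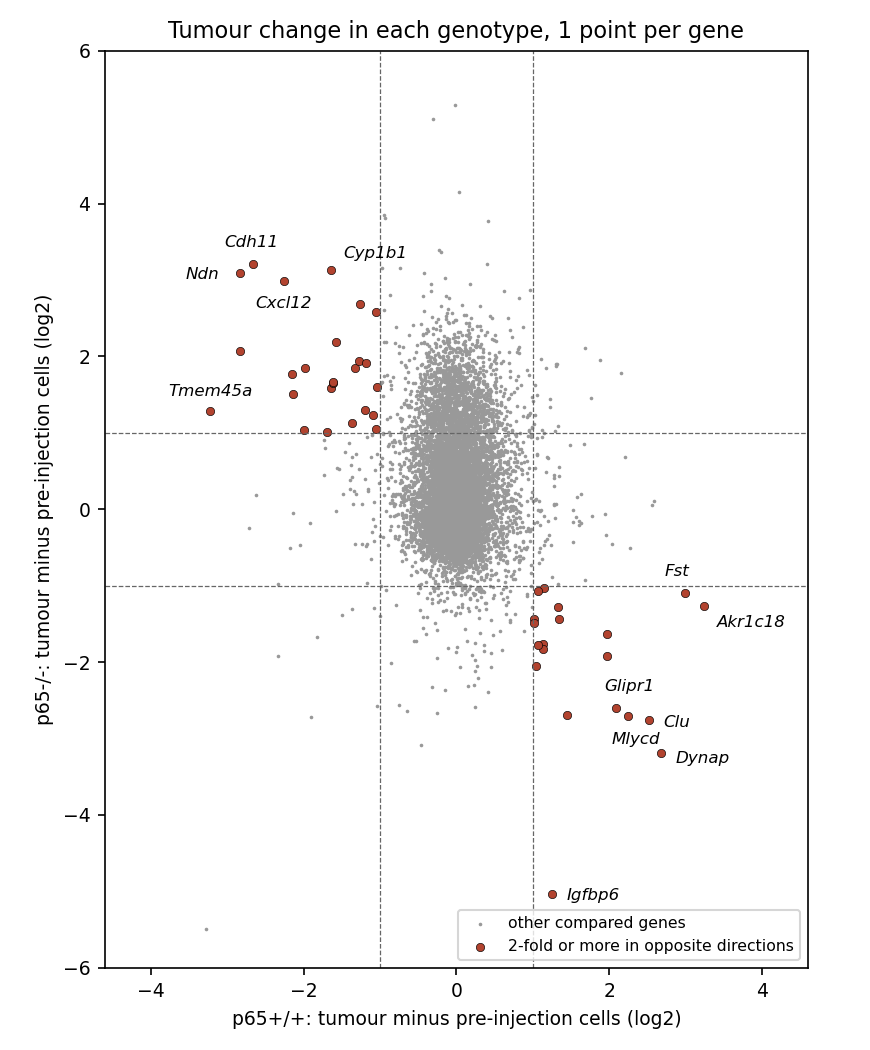
Log2 difference between tumour and pre-injection cells in p65+/+ cells (horizontal axis) and p65-/- cells (vertical axis), 1 point per gene compared in both genotypes, with dashed lines at the 2-fold threshold. The 45 red points are the 20 genes higher in p65+/+ and lower in p65-/- tumour cells and the 25 genes that go the other way.

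**Figure D3:**
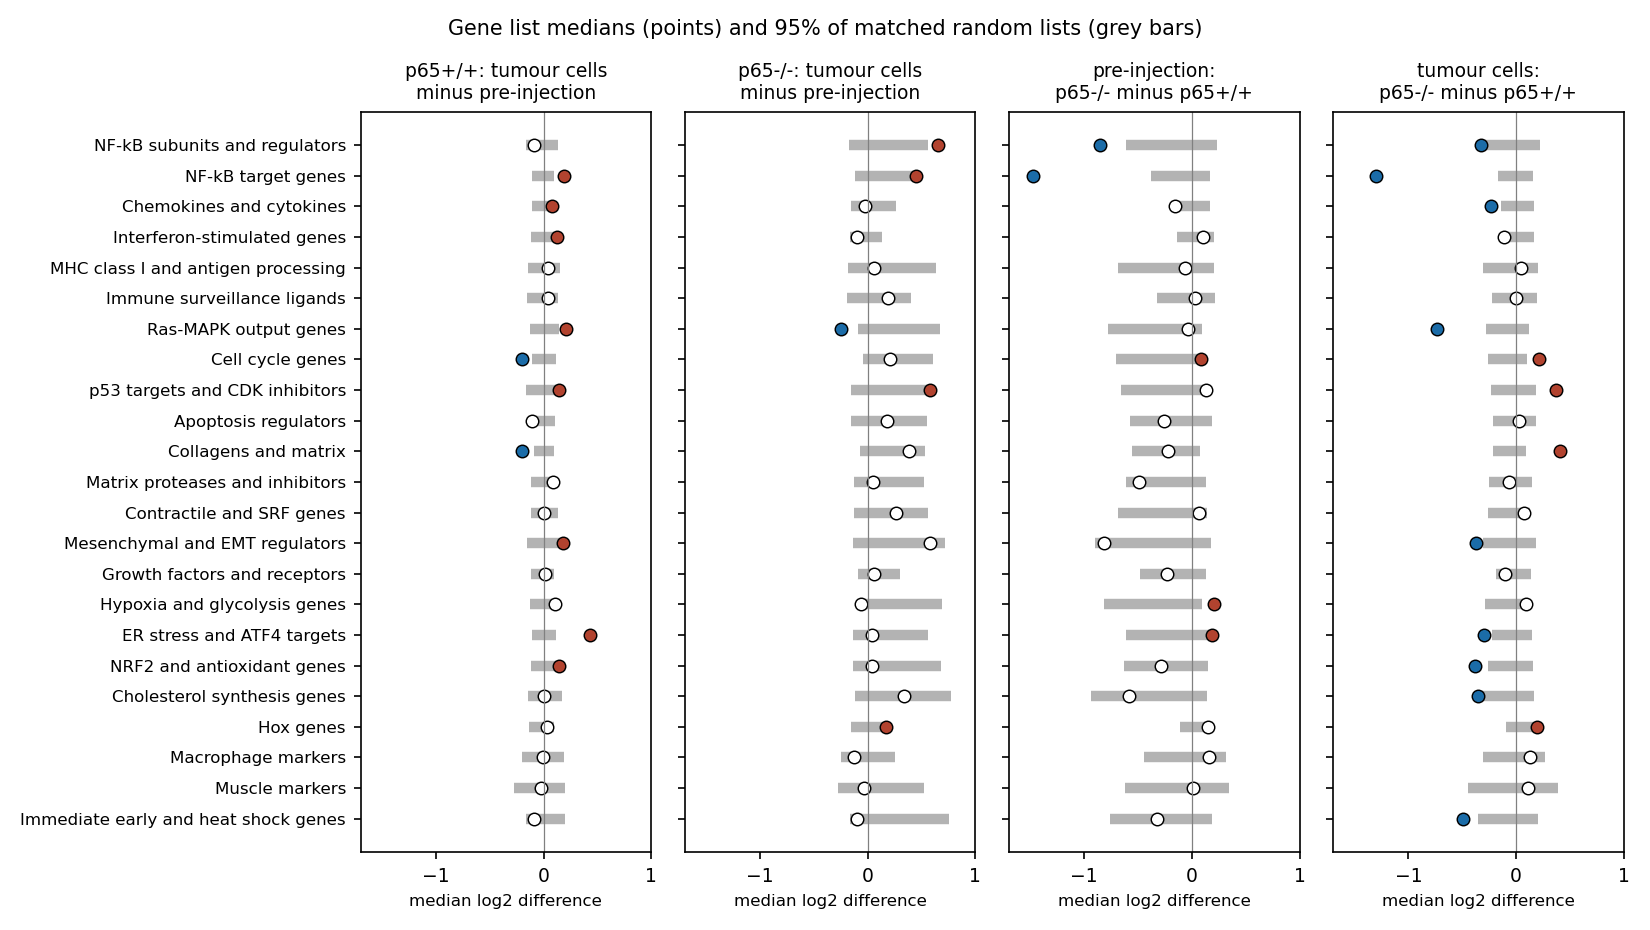
Median log2 difference of each gene list with at least 5 compared members, 1 panel per comparison, shown as points, with grey bars for the middle 95% of random lists of similar signal. Red points lie above and blue points below that range, and NF-kB target genes lie below it in both comparisons of p65-/- with p65+/+ cells, at -1.48 and -1.31.

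Few markers of macrophages, endothelium and lymphocytes passed the floor. The leukocyte gene Ptprc, the macrophage genes Lyz2 and C1qa and the endothelial genes Cdh5 and Kdr lay under it on all 4 arrays. Macrophage markers had 0 of 6 higher and 0 lower in p65+/+ tumour cells, and 1 of 7 higher, Tyrobp at least 3.17-fold, and 0 lower in p65-/- tumour cells. In p65-/- against p65+/+ cells 2 of 6 were lower before injection, such as the co-receptor gene Cd14 at 2.25-fold, with 0 higher, and in tumour cells 1 of 7 was lower, Cd14 at 3.68-fold, and 1 higher, Tyrobp. Endothelial markers had no member at 2-fold in either tumour change (0 of 4 and 0 of 6) or between genotypes in tumour cells (0 of 6), and before injection 1 of 6 was lower in p65-/- cells, the receptor gene Flt1 at 4.30-fold. Lymphocyte and granulocyte markers had 0 members at 2-fold in the 4 comparisons, among 3, 5, 5 and 4 compared. Muscle markers had 1 of 5 higher in p65-/- than in p65+/+ tumour cells, Myh3 at 2.26-fold, for which the authors' deposited table gave a log2 difference of -3.22, and 0 at 2-fold in the other 3 comparisons. Adipocyte markers had 1 of 3 higher in p65-/- pre-injection cells, Cebpa at 2.39-fold, and 0 at 2-fold in the other 3 comparisons. Among epithelial markers Krt19 was the 1 member at 2-fold, of 5, 6 and 5 compared, at least 3.62-fold higher in p65-/- than in p65+/+ pre-injection cells, 6.49-fold higher in p65-/- tumour than pre-injection cells and at least 23.7-fold higher in p65-/- than in p65+/+ tumour cells, and 0 of 1 were higher or lower in p65+/+ tumour cells.

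Genes of antigen presentation and of recognition by immune cells were covered in part. A probe set of their own was present for 16 of 20 MHC class I and antigen processing genes and 22 of 29 immune surveillance ligands. Raet1a, Raet1b, H60a, H60b and H2-T23 were among those without one. Of all compared genes, 1.72% differed by 2-fold in the p65+/+ and 15.2% in the p65-/- tumour change. Between genotypes the share was 19.9% before injection and 8.12% in tumour cells. No difference from these shares was tested. MHC class I and antigen processing genes had 0 of 13 higher and 0 lower in p65+/+ tumour cells (percentile 74.2) and 0 of 12 and 0 between genotypes in tumour cells (percentile 70.6). In p65-/- tumour cells 2 of 12 were higher, such as the chaperone gene Canx at 3.06-fold (percentile 40.6), and before injection 2 of 13 were lower in p65-/- cells, with Canx at 2.70-fold (percentile 54.3). Immune surveillance ligands had 1 of 11 lower in p65+/+ tumour cells, Cd276 at least 2.30-fold (percentile 76.5, standing apart under 1 of 7 alternatives), and in tumour cells 1 of 12 was higher in p65-/- cells, Cd276 at least 3.47-fold (percentile 42.4). In p65-/- tumour cells 1 of 10 was higher, Cd47 at 2.21-fold, and 1 lower, the growth factor gene Tgfb1 at 2.03-fold (percentile 86.7), and before injection 1 of 12 was lower in p65-/- cells, Cd47 at 2.76-fold (percentile 56.1). Interferon-stimulated genes had 2 of 20 higher in p65-/- tumour cells, Ifit2 at least 3.91-fold and Irgm1 at 3.66-fold (percentile 15.2), and 1 of 20 lower in p65-/- pre-injection cells, Ifit2 (percentile 76.0, standing apart under 1 of 8 alternatives). Between the tumour cells of the 2 genotypes 1 of 19 was higher in p65-/- cells, Irgm1 at 5.69-fold, and 1 lower, Rtp4 (median -0.11, percentile 3.17). Contractile and SRF genes had 4 of 18 lower in p65-/- pre-injection cells, such as Myl9 at 2.96-fold, and 1 higher, Ccn2 at 4.08-fold (median 0.07, mean -0.14, percentile 91.7, standing apart under 2 of 8 alternatives), and immediate early and heat shock genes 1 of 12 lower, Hspb1 at 6.16-fold, and 0 higher (percentile 23.1). Of the sex-linked genes 1 was compared in p65-/- tumour against pre-injection cells and between genotypes in tumour cells, Eif2s3y, at least 2.61-fold and at least 2.48-fold higher, and 0 were compared in the other 2 comparisons.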

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

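The tests of a genotype difference in both states, of long genes as the whole cause and of host cells were chosen only after the result was seen, and the differences between genotypes given here were not tested, since each group has 1 array. Tumour and pre-injection cells differed by 2-fold or more in opposite directions in the 2 genotypes for 45 genes, 20 higher in p65+/+ and lower in p65-/- tumour cells and 25 lower in p65+/+ and higher in p65-/- tumour cells. The difference between the tumour changes, in favour of p65-/- cells, was largest, among genes with all 4 arrays above the floor, at 5.24 on the log2 scale for Cxcl12, 4.81 for Fbln2, 4.74 for Cd24a, 4.51 for Tmem45a and 4.11 for Hs6st2, whose p65+/+ tumour change was 0.04. In the other direction it was -4.95 for Mlycd, -4.69 for Glipr1, -4.08 for Fst, -3.60 for Slc6a17 and -2.97 for Itgb7.

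The p65-/- pre-injection array had 2245 genes at least 2-fold lower and 259 higher than the p65+/+ pre-injection array, and a genotype difference present in both states as the whole cause is argued against, since the lower genes compared in both states had a median log2 difference of -1.56 before injection and of -0.39 in tumour cells (95% bootstrap interval -0.42 to -0.36), under 50% of the size, although selection alone makes some decrease expected. Array-wide scaling stays open: after quantile normalization 63.2% of the genes that differed were lower instead of 89.7%, between the limits set for and against it, while 83.2% were lower with cyclic loess and 86.45% with median centring, which left most of the excess in place, and the scaling by the authors is not given in the sources used here. A loss of signal from long genes on that array is consistent with the data, since the gap in median log2 difference between the longest 20% and the shortest 20% of genes was -0.40 before injection and -0.09 in tumour cells (extra gap -0.32, 95% bootstrap interval -0.38 to -0.28). As the whole cause it is argued against: among the shortest 20% of genes 8.80% were lower and 2.99% higher before injection and 4.70% and 2.86% in tumour cells, an extra excess of 3.97 percentage points (95% bootstrap interval 2.48 to 5.47). The bootstrap intervals came from resampling genes within these single arrays. Genes are not independent replicates, and variation between arrays or lines of cells is not in the intervals. What is argued against here is thus argued for these arrays only. A difference that p65-/- cells had before injection and no longer had as tumour cells stays open and was not tested.

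In p65-/- cells 1705 genes were at least 2-fold higher in tumour than in pre-injection cells and 184 lower. Host cells carried over from the tumour are argued against as the cause of the whole excess: the added signal would need a share of at least 13.0%, which would raise Rela by 0.81 log2 if host cells had the p65+/+ level, and Rela differed by -0.032 log2. The macrophage marker Tyrobp, at least 3.17-fold higher, and the Y-linked gene Eif2s3y, at least 2.61-fold higher, go the other way, so a smaller share of host cells stays open. Tyrobp was the only 1 of 7 compared macrophage markers at 2-fold, and Ptprc, Lyz2 and C1qa lay under the floor on all arrays. Eif2s3y was the only 1 of 4 sex-linked genes with a probe set of their own that passed the floor in this comparison. Return of a low pre-injection signal to the level of the other arrays is consistent with 5.92% of the 1705 genes lying at least 2-fold above the p65+/+ pre-injection array. A biological change in p65-/- cells during tumour growth, return to culture or hygromycin selection stays open for these genes and was not tested.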

How the results depend on the processing

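The 75th percentile scaling, cyclic loess and the substitution of the p65-/- tumour array were tried only after the data were seen. The sample titles link the pre-injection and tumour arrays of each genotype, and each tumour change is the difference within such a pair. With 1 pair per genotype no paired test was possible. An additive fit of genotype and state over the 4 arrays was possible but not used, since its 1 residual degree of freedom is the difference of the tumour changes. The planned re-summarising from the scanner intensities was not run, since no map of cells to probe sets was used here. Scaling mattered most for the p65-/- pre-injection array: quantile normalization moved the median log2 difference of all genes to 0.24 for the genotype difference before injection and to -0.18 for the p65-/- tumour change, and 75th percentile scaling moved them to 0.35 and -0.25. The share of lower genes among those that differed before injection went from 89.7% to 63.2%, 64.99% with 75th percentile scaling, 65.3% in the authors' table and 67.3% with the substituted array, but lay between 83.2% (cyclic loess) and 94.5% (4-fold) under the other 7 alternatives, including 86.45% with median centring. That of the p65-/- tumour change went from 9.74% to 26.7%, 24.7% and 33.2% with the first 3 and lay between 7.22% and 14.5% under the others. With quantile normalization the p65-/- tumour change had 428 lower genes, the genotype difference before injection 886 higher genes and the difference of the tumour changes 646 lower genes. With 75th percentile scaling these were 357, 795 and 617, while 1088 genes were higher in the p65-/- tumour change, 1476 lower before injection and 1191 higher in the difference of the tumour changes. The substituted array gave 450 lower genes. In the authors' table of quotients the p65+/+ tumour change had 605 higher and 616 lower genes, the p65-/- tumour change 1027 lower, the genotype difference before injection 1197 higher and in tumour cells 957 higher and 1164 lower, and the difference of the tumour changes 1117 lower. In that table the correlation of the genotype differences was -0.0027, the share of lower genes between genotypes in tumour cells 54.9% instead of 67.4%, and 2 named genes, Mospd1 at -0.31 and Myh3 at -3.22 in tumour cells, changed direction; the cause was not tested. A floor at the 70th percentile, which leaves fewer genes to compare, gave 47 lower genes in the p65+/+ and 103 in the p65-/- tumour change, 154 higher before injection and 187 higher in tumour cells, with median shifts to -0.19 before injection and 0.14 in the p65-/- tumour change. With no floor 175 genes were lower in the p65+/+ tumour change, a share of 54.4% instead of 44.3%, and 476 in the difference of the tumour changes. The mean of all probe sets gave 1090 higher genes in the p65-/- tumour change. At 4-fold, a stricter threshold by construction, the counts of higher and lower genes were 16 and 16 in the p65+/+ and 213 and 29 in the p65-/- tumour change, 33 and 564 before injection, 58 and 121 in tumour cells and 305 and 59 for the difference of the tumour changes. Counts under median centring, cyclic loess and a floor at the 25th percentile stayed within 1.5 times those with the deposited values. Of 322 values of named genes, all 322 moved by no more than the within-gene standard deviation of probe sets under cyclic loess, as did 274 under quantile normalization, where 48 moved by more. By the same measure 156 moved with the floor at the 70th percentile, 103 with the mean of all probe sets, 76 in the authors' table besides the 2 that reversed, and 72 each with the floor at the 25th percentile and with no floor. Median centring and 75th percentile scaling add 1 constant to all genes of a comparison, so they cannot change the place of a list and were left out of tallies. Of 100 placements of a list in a comparison, 33 stood apart with the deposited values, 18 of them under all other alternatives, and 20 of the other 67 stood apart under at least 1 alternative. Rela kept its direction in both genotype comparisons under every alternative run for it. Genes near the floor are limited by background, so their folds are lower bounds.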

Other observations

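The tests in this part, of a lost segment, of a general low signal and of imprinted genes, were chosen only after the result was seen. Mtap, Cdkn2a and Cdkn2b are neighbours in the gene table, and all were lower on both p65-/- arrays. Mtap, which salvages methionine, had 4 probe sets that were 12.3-fold, at least 8.15-fold, at least 23.5-fold and at least 23.1-fold lower before injection, and 17.3-fold, at least 8.91-fold, at least 27.8-fold and at least 27.0-fold lower in tumour cells. Of 11699 genes put in order along the chromosomes, 394 were lower on both p65-/- arrays, and they formed 2 runs of 3 neighbours, this one and Psmc6, Styx and Gnpnat1. In 1000 shuffled orders the mean number of such runs was 0.407, the highest was 3 and 57 had 2 or more.

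A candidate explanation is the loss, in the p65-/- line, of the chromosome segment that holds these genes. It stays open: the genes were found by their main probe sets, and the 3 further probe sets, which were also at least 2-fold lower on both p65-/- arrays, all belong to Mtap. On the p65-/- tumour array the differences of all these probe sets were -2.003 log2 or lower. The general low signal of the pre-injection array is argued against for Mtap, whose 3 further probe sets were at least 8.91-fold lower on the p65-/- tumour array. For Cdkn2a and Cdkn2b this check cannot decide, since they were picked as lower on both p65-/- arrays. Silencing of the segment or a difference between the embryos that gave the lines was not tested and stays open. With 1 line per genotype, genes that differ between the p65-/- and p65+/+ lines cannot be assigned to Rela.

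Several imprinted genes, which are expressed from 1 parental copy, differed in opposite directions in the tumour changes: Ndn, Peg12 and Slc38a4 were at least 7.14-fold, at least 4.45-fold and 3.98-fold lower in p65+/+ tumour cells, and 8.56-fold, at least 3.42-fold and 2.05-fold higher in p65-/- tumour cells. A shared change of imprinted genes as a class was set up as a hypothesis on a textbook list of 37 genes, which had 3 of 18 lower and 0 higher in p65+/+ tumour cells, at percentile 9.01 of random lists, and 6 of 20 higher and 0 lower in p65-/- tumour cells, at percentile 97.7. With the mean of all probe sets of a gene the percentiles were 2.80 and 99.7. Then 5 of 17 were lower in p65+/+ tumour cells, now including Meg3 and Dlk1. In p65-/- tumour cells 4 of 16 were higher, no longer including Ube3a and Impact. The p65+/+ percentile lies inside the middle 95% of random lists with both ways of taking the gene value, so a change of the class stays open. Ndn, Peg12 and Slc38a4, which prompted the hypothesis, are the 3 lower members with 1 probe set per gene. They are also among the 6 higher members in p65-/- tumour cells, so these counts partly restate the observation. The p65-/- tumour change also contains the low p65-/- pre-injection array. With 1 probe set per gene Sgce differed on the log2 scale by -0.89 and 0.83 and Copg2 by -0.50 and 0.94 in the p65+/+ and p65-/- tumour changes. Meg3 went the other way by that value, at 0.145 and -0.21. It was nevertheless lower in 5 of its 9 compared probe sets in the p65+/+ and higher in 5 of 8 in the p65-/- tumour change. Members with a positive p65+/+ tumour change also included Impact at 0.41, Snrpn at 0.18, Igf2r at 0.17, Dlk1 at 0.16 and Magel2 at 0.15.

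Gene length and signal were also set against each other. Before injection, the median log2 difference between p65-/- and p65+/+ cells was 0.11, 0.07, -0.04, -0.24 and -0.29 in 5 groups of genes of increasing length, with median lengths of 4.05, 11.6, 22.7, 44.2 and 115 kb. In tumour cells the genotype difference was 0.05 in the shortest and -0.03 in the longest group, and the p65+/+ tumour change was -0.02 and 0.01. The share of probe pairs in which the cell of an odd row was brighter than that of the next row was 71.0% on the p65-/- pre-injection array, and 75.5%, 74.3% and 73.4% on the p65+/+ pre-injection, p65+/+ tumour and p65-/- tumour arrays.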
